A study of Escherichia coli with 7 samples.

How the data were processed

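RNA from Escherichia coli grown in chemostats was compared on 2-colour oligonucleotide arrays, with an irradiated culture and a culture that was not irradiated on each array. The series holds 7 arrays. They cover 3 runs after 1 h of UVA light, 3 runs after 50 h, and a second array of run 2 at 1 h on which the dyes were exchanged (the dye swap). Per the series' design text, the runs were 3 separate biological experiments and 1 replicate was dye-swapped. On the 6 unswapped arrays the irradiated sample carried Cy3 and the control Cy5, per the labels. The 50 h arrays are all of 1 dye orientation, per the labels.

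Per the series' design text, the authors used a commercial array with 4288 gene-specific probes, quantified spots and background with Affymetrix Jaguar 2.0, and formed an induction factor from the Cy3 and Cy5 signals in GeneSpring. Spots with a signal below 50 were left out, the smallest factor was set to 0.01, and values were normalized on the 50th percentile after background correction. The deposited values are log10 ratios of the 2 dyes. The log10 base was not stated and was read from the values: values that recur within an array lay apart by the log10 of a ratio of whole numbers of at most 20 (within 1e-06) in 76.2% to 100% of the comparisons per array, and in 0% on a log2 or natural log scale. The medians of the deposited arrays, on the log2 scale, were 1.03, 0.15 and 0.27 for runs 1 to 3 at 1 h, 0.89 for the dye swap, and 0.58, 0.48 and 0.37 for runs 1 to 3 at 50 h. They were thus not at 0 after the stated percentile normalization, and where the authors centred the values stays unknown.

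The direction of the deposited ratios was not stated. They are likely Cy3 over Cy5, which is irradiated over control on the unswapped arrays, because the design text calls them induction factors. The sign of every value rests on this reading. The dye swap was taken as deposited in its own dye orientation, so its sign was turned. The turning was part of the planned test. A check chosen after the results were seen used pairs of neighbouring genes printed apart on the array. Across such pairs the difference of run 2 and its swap as deposited correlated with r = 0.115 (SE 0.0226), against 0.0459 (SE 0.0168) for their sum. After turning, the swap correlated across genes with run 2 (r = 0.165) and with run 3 (r = 0.199) but was negatively correlated with run 1 (r = -0.281).

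The table holds 4608 probes. The deposited annotation gave 4087 of them 1 gene each, 521 no gene, and 0 several genes. Of the 4087, 4086 matched a gene of the RefSeq annotation of assembly ASM584v2 of strain K-12 substr. MG1655, which was used only for names and for the order of genes, and 197 symbols were updated to its current ones. A pair of probes was present for 49 genes, and each probe was tested separately. The 4 numbers in each probe's identifier were read as its place on the array. By this reading, which the files do not state, the probes form 1152 sets of 4 at 1 position, mostly neighbours on the chromosome.

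Values were converted to log2, values at or below the ratio of 0.01 were set to missing (6 in run 1 at 1 h, 4 in the dye swap of run 2, and 1 each in runs 2 and 3 at 50 h), and each array was centred on its median. The dye swap was turned and averaged with run 2, so that n was 3 at each time. A probe was tested at a time only with values in all 3 runs. This left 3781 probes at 1 h, 2459 at 50 h and 2277 for the difference of the times. The arrays held 3892, 4453 and 4488 values in runs 1 to 3 at 1 h, 3958 in the dye swap, and 4563, 2853 and 3190 in runs 1 to 3 at 50 h. The number of arrays limits the precision. Spot signals and backgrounds were not used here, so signal over background was not checked.

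A linear model with 1 mean per time was fitted in limma 3.58.1 (R 4.3.3) with a spread shared by both times, moderated by empirical Bayes. The comparisons were the mean at 1 h, the mean at 50 h, and 50 h minus 1 h, which used the spread between runs and did not pair run numbers. P-values were adjusted by Benjamini-Hochberg over the probes of each comparison, and adjusted p under 0.05 was called past the test. Since the spread is shared, a gene with scattered runs at 1 h can miss the test at 50 h. Correlations were across genes, which are not independent replicates. The 30 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 genes among the 2277 were tested with camera (preset correlation 0.01), and each list's genes were also adjusted over the list alone.

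The rule named, per time, up to 10 genes per direction with the largest mean among those past the test with 1 sign in all runs. Where fewer than 10 passed, it filled up to 5 with the lowest unadjusted p among genes with 1 sign in all runs and a mean of at least 1 in size on the log2 scale. For the difference it named up to 5 genes per direction in the same way, with all runs of 1 time above all runs of the other, and for each list discussed up to 4 members with the lowest unadjusted p at either time. It also fixed 22 genes of DNA repair, oxidative stress, amino acid synthesis and growth control. Probes without a gene name were not named. Genes outside the rule that are named as neighbours on the array or the chromosome, or from a count of 5 or fewer in an alternative, as well as ydhL, glnK, mtlD and glnS, were chosen after their values were seen.

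The procedure was tested on simulated data with the missing values of the deposited table. These data had independent normal noise on each array, no dye effect and a set number of changed probes. The shares recovered therefore need not hold for the real arrays. At 1 h (3787 probes) it recovered 6% of log2 changes of 1, 72% of 2, 96% of 3 and 100% of 4, with 1 false call among 138. At 50 h (2458 probes) the shares were 14%, 82%, 98% and 95.9%, with 9 false calls among 153, and for the difference (2279 probes) 2.3%, 53.2%, 93.3% and 93.8%, with 7 among 240. Lists shifted by 1 were called in 2 of 2 cases at 50 h, beside 1 list that was not shifted, and in 2 of 2 for the difference, beside 0 others.

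Alternatives planned before the data were examined were values not centred, arrays scaled to 1 median absolute deviation, quantile normalization, probes with at least 2 runs, values at the minimum ratio kept, run 2 by either array alone, each time fitted alone, robust empirical Bayes, treat with a 1.2-fold minimum, run numbers as a block, a dye term, a 2-fold rule without a test, estimated correlation and fry for the lists, and leaving out each run. Named probes only, a dye term without a random block, and the swap read as already turned were added after the data were seen. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.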

Results

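Transcript ratios of irradiated over control chemostat cultures of Escherichia coli were measured on 7 arrays, with 3 runs after 1 h of UVA light (run 2 also as a dye swap) and 3 runs after 50 h. Per the series' title, the study asks how gene expression adapts to artificial sunlight. The comparisons ask which transcripts differ early, which differ after long exposure, and whether the times differ. Arrays held between 2853 and 4563 values for 4608 probes. Values are log2 ratios, likely irradiated over control since the design text speaks of induction factors, with each array's median at 0, given as mean ± SD (n = 3 runs). Changes are thus relative to the median of the array, which lay between 0.15 and 1.03 on the log2 scale as deposited.

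After 50 h, amtB, the gene of the ammonium transporter, rose by 4.20 ± 1.13 on the log2 scale, 18.4-fold. It was the 1 named gene past the test that was higher, and it was higher on all 7 arrays after the swap was turned. The transcript of glnK, the neighbouring gene of a regulator of this transporter, stood at -1.14 ± 0.37 (limma, adjusted p 0.420), so the rise was not seen there. By the reading of the identifiers, the probe printed directly beside that of amtB is of the gene ykfG. After 50 h ykfG was also high, at 3.03 and 5.09 in runs 1 and 3, against 3.08 and 4.19 for amtB, and it lacked run 2. Whether these spots share an effect of their place on the array was not tested. The wobble-base tRNA modification gene cmoB changed by -4.65 ± 1.21, 25.1-fold lower. Its chromosomal neighbour torY, for a cytochrome of trimethylamine N-oxide respiration, changed by -2.88 ± 0.35, 7.37-fold lower. The CRISPR adaptation genes cas2 and cas1 changed by -3.90 ± 0.52 and -3.10 ± 0.12, 14.9-fold and 8.56-fold lower.

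Among metabolic genes, abgB, for a subunit of the enzyme that cleaves p-aminobenzoyl-glutamate, changed by -4.47 ± 0.14 after 50 h, 22.2-fold lower. The leader peptide gene ilvL, ahead of the isoleucine and valine synthesis operon, changed by -3.60 ± 0.32, 12.2-fold lower, whereas ilvM of that operon stood at -0.23 ± 2.18. The repressor gene mtlR of mannitol uptake changed by -2.51 ± 0.50, 5.71-fold lower, beside mtlD for mannitol-phosphate dehydrogenase at -1.90 ± 0.41 (limma, adjusted p 0.089). The Rac prophage gene ydaG changed by -3.77 ± 0.16, 13.7-fold lower, the regulator gene yieP by -3.05 ± 0.26, 8.30-fold lower, and the fimbria-like gene yfcO by -2.91 ± 0.40, 7.53-fold lower. The gene ydhL of unknown function, named after its value was seen, changed by -2.17 ± 0.58.

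**Figure D1:**
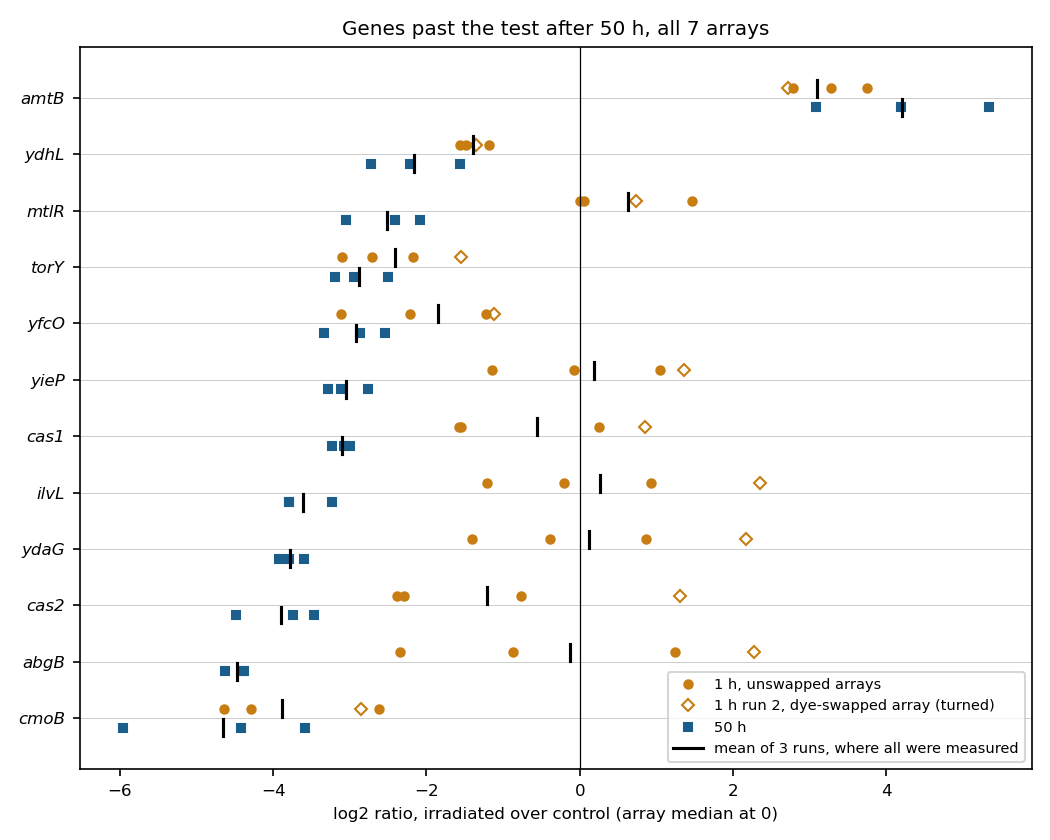
Log2 ratios (likely irradiated over control, array median at 0) of the 12 named genes past the test after 50 h, 1 point per array, with circles for 1 h, open diamonds for the turned dye swap of run 2 at 1 h, squares for 50 h and bars for the mean of 3 runs. amtB was higher on every array (mean 4.20 after 50 h), and cmoB, torY, yfcO and ydhL were lower on every array.

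In limma, 16 of 2459 probes passed the test after 50 h, 3 higher and 13 lower. Of these, 12 had a gene name, 1 higher and 11 lower, and 4 had none. Adjusted p (limma) was 0.029 for amtB, cas2, torY and yfcO, 0.034 for cmoB and cas1, 0.037 for ydaG, 0.038 for ilvL, and 0.0499 for abgB, yieP, mtlR and ydhL, each with 1 sign in 3 of 3 runs. At an unadjusted p under 0.05, 515 probes passed, and 1276 (51.9%) had 1 sign in all 3 runs, where chance gives 25% if signs are independent. The 50 h arrays share 1 dye orientation, so a dye effect of each gene would also raise this share. Not past the test, the ferritin gene ftnA stood at 2.81 ± 0.20, yffQ at 2.07 ± 0.40, the fimbria gene fimF at 2.20 ± 0.40 and yraH at 1.96 ± 0.56, with adjusted p from 0.056 to 0.070 in limma. With a dye term ftnA stood at 1.30 (its turned swap was -1.69) and yffQ at 0.97, while fimF stood at 2.48 and yraH at 2.05.

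The number of calls depended on the scaling: it was 23 (2 higher, 21 lower) with quantile normalization and 5 (2 higher, 3 lower) with arrays scaled to 1 median absolute deviation. It was 0 without run 2 or 3 of either time, with 50 h fitted alone, with run 2 at 1 h taken from the swap alone, and with a dye term. Without run 1 at 50 h it was 12, of which 10 were higher and 4 were among the 16, and without run 1 at 1 h it was 37. Direction was the same for all 16 in each of these settings. Only with the dye term could it have changed. In the others it was fixed in advance, since the 16 had 1 sign in all 3 runs at 50 h. Quantile normalization keeps the order of values within an array, and the 16 lay well away from the array median. The dye swap at 1 h, as deposited and not turned, had the sign of the 50 h value in 11 of the 16, and after turning it had that sign for amtB, cmoB, torY, yfcO and ydhL.

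Several of the lower genes are neighbours on the chromosome and share 1 printed position by the reading of the identifiers. Such a position is the same place in 4 blocks of the array, so its spots do not lie side by side. The genes cas1 and cas2 share a position with cysD at -2.09 ± 0.41 and iap at -0.54 ± 1.76, and cmoB and torY share one with cutC at -0.78 ± 0.10. The position of cmoB also holds torZ, which lacked run 2 and was low at -2.82 and -3.44 in runs 1 and 3. The position of ilvL holds yifB at -3.62 ± 0.17 and maoP at -2.81 ± 0.44, and that of yieP holds hsrA at -2.07 ± 0.19. The position of abgB holds abgA at -4.49 ± 0.11. The genes of the positions of ilvL and yieP also follow each other in the chromosomal order of genes with a probe. There the low values span 2 positions, both in the same printed row. Their locus tags are not consecutive, however, with b3755 for yieP and b3764 for maoP. The other measured neighbours on the chromosome printed at other positions had means nearer to 0 than the call or of the other sign, such as casD at -0.47 ± 0.41, casC at 0.73 ± 0.49 and casB at -1.02 ± 0.79 near cas1, and yecN above 1, cmoA at -0.63 ± 0.22, argS at 0.50 ± 0.53 and flhE at 0.71 ± 0.77 near cmoB and torY. Of the 16 probes past the test, 6 lie in pairs at 3 positions. The 20 other probes with all runs at the positions of the calls had the sign of the call in 13 cases, 10 of them at a size of at least 1, a size that 21.2% of all tested probes reached.

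After 1 h no gene passed the test, so the following are values only. The gene ykfG, a prophage gene of the RadC family, stood at 3.47 ± 0.28 (11.1-fold), the copper efflux pump gene cusA at 3.21 ± 0.47 (9.24-fold) and amtB at 3.10 ± 0.27 (8.56-fold). The probes of ykfG and amtB are printed directly beside each other by the reading of the identifiers, and both were also high after 50 h in the runs measured. The cell wall recycling gene murQ stood at 2.10 ± 0.40 and yjbM at 2.13 ± 0.64. On the lower side, cmoB stood at -3.89 ± 1.01 (14.8-fold) and torY at -2.40 ± 0.28 (5.29-fold). Aspartate ammonia-lyase (aspA) stood at -3.25 ± 0.56, the peroxide reductase subunit ahpF at -3.23 ± 0.86 and isocitrate lyase (aceA) at -2.14 ± 0.46. These 10 genes had 1 sign in 3 of 3 runs. The smallest adjusted p was 0.111 in limma, shared by 8 of them, with 0.126 for murQ and 0.159 for yjbM.

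In limma 0 of 3781 probes passed after 1 h, against 511 at an unadjusted p under 0.05. Of the probes, 1553 (41.1%) had 1 sign in all 3 runs, where chance gives 25% if signs are independent. Most 1 h arrays share 1 dye orientation, so a dye effect would raise this share too. The count was 3 with arrays scaled to 1 median absolute deviation (ahpF, ykfG, amtB) and 10 with quantile normalization. With the swap left out it was 6, which included ahpC, and with a dye term over all arrays it was 76, with 0 at 50 h. That fit takes all arrays as independent, so run 2 and its swap count as separate replicates although they are of the same run. The turned swap and run 2 correlated across genes with r = 0.165 and the turned swap and run 1 with r = -0.281, against 0.285 to 0.493 among the unswapped arrays.

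The fixed genes did not pass the test at either time. The peroxide reductase gene ahpC stood at -3.61 ± 1.33 after 1 h (limma, adjusted p 0.111) and -1.75 ± 0.60 after 50 h (0.167), but its turned swap value was 0.35 and with a dye term its 50 h value was 0.70. The catalase gene katG stood at 1.17 ± 0.60 after 1 h, the superoxide regulator soxS at 0.22 ± 0.53 and the DNA-protecting dps at -0.02 ± 0.49, with dps at 0.70 ± 0.65 after 50 h. Superoxide dismutase (sodA) was at 1.85 ± 3.44 after 50 h, and at -0.14 without run 3, and the iron regulator fur was at -0.76 ± 0.61 and -0.85 ± 0.52 at the times in order, or -0.20 and -0.06 with a dye term.

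Of the fixed DNA repair genes, recA lacked runs at both times. The cell division inhibitor sulA stood at -0.30 ± 0.42 after 1 h, the polymerase subunit umuD at 0.15 ± 1.02 and the photolyase phr at -0.04 ± 0.07, with phr at 0.82 ± 2.00 after 50 h, or -0.33 without run 3. The tRNA thiolation gene thiI, whose product makes the main UVA-absorbing tRNA base, stood at 0.68 ± 0.29 after 1 h.

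In amino acid synthesis, ilvD lacked runs, ilvC stood at -1.24 ± 1.68 after 1 h and -0.03 ± 0.87 after 50 h, and leuA at -0.93 ± 0.75 and 0.90 ± 1.08, the latter 0.32 without run 3. Histidine gene hisG stood at -0.99 ± 0.31 after 1 h and glutamate synthase gltB at 0.62 ± 1.00. Methionine synthase metE stood at 0.60 ± 0.37 and 0.24 ± 0.12, and sulfate-activating cysD at -0.65 ± 0.77 and -2.09 ± 0.41. The alarmone genes relA and spoT stood at -0.09 ± 0.65 and -0.86 ± 1.71 after 1 h and at -1.60 ± 0.60 and -0.61 ± 0.24 after 50 h, and relA shares its printed position with mazE and mazF. The stress sigma factor rpoS stood at 0.45 ± 0.55 and -0.56 ± 0.38, and the glucose transporter ptsG at -0.89 ± 0.07 after 1 h. With a dye term the signs of phr, soxS, dps, gltB and relA after 1 h, of ilvC at both times, and of metE, spoT and rpoS after 50 h turned, as did those of some others of these genes when 1 run was left out or arrays were not centred. The smallest adjusted p among the fixed genes was 0.070 in limma, for cysD after 50 h.

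**Figure D2:**
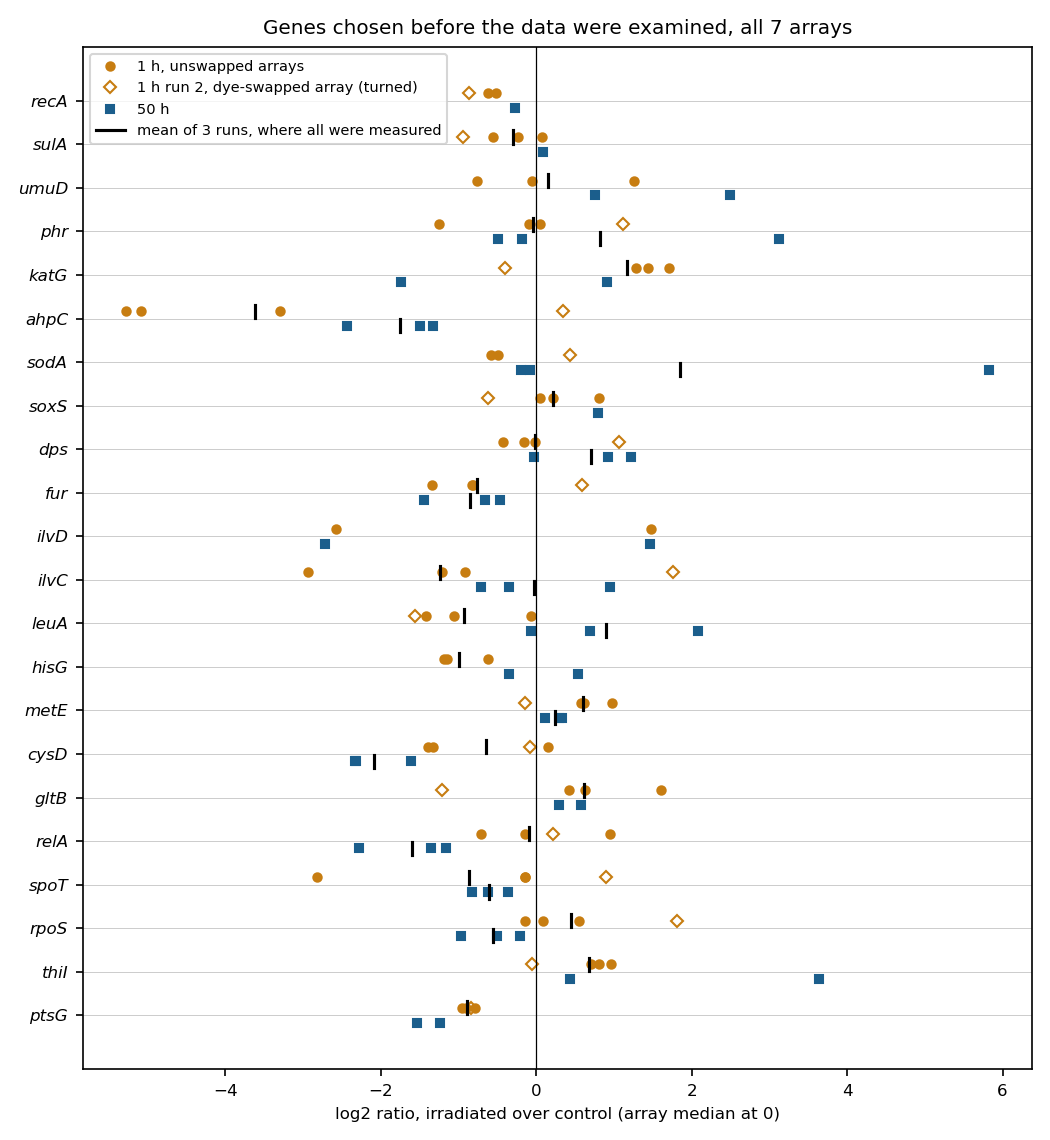
Log2 ratios (likely irradiated over control, array median at 0) of the 22 genes chosen before the data were examined, 1 point per array, with circles for 1 h, open diamonds for the turned dye swap, squares for 50 h and bars for the mean where all 3 runs were measured. ahpC lay at -3.61 after 1 h while its turned swap lay at 0.35, and none of these genes passed the test.

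Between 50 h and 1 h no gene passed the test. The rule named the genes with the lowest unadjusted p whose runs at 1 time all lay above those at the other, and not the largest differences. As 50 h minus 1 h with the standard error, these were the ribosomal protein gene rplO at 2.86 (SE 0.69), the histidine-binding hisJ at 2.63 (0.56), the envelope protease rseP at 2.43 (0.46), ydiB at 1.88 (0.38) and cdgI at 1.77 (0.40). In the other direction, ydaG stood at -3.90 (0.69), ilvL at -3.87 (0.69) and mtlR at -3.14 (0.53). The channel gene mscM stood at -2.75 (0.47), and the lactate regulator lldR, which shares the printed position of mtlR, at -2.47 (0.47). All had a limma adjusted p of 0.256, as did abgB at -4.34 and yieP at -3.24, which are outside the rule. In limma 0 of 2277 probes passed, against 233 at an unadjusted p under 0.05. Without run 1 at 1 h, 4 passed, which were ilvL, ydaG, abgB and 1 probe without a name. Genes past the test at 50 h only are therefore not shown to differ from 1 h.

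Across 2277 probes the means after 1 h and after 50 h correlated with r = 0.311, and genes are not independent replicates. Without run 1 at 1 h, r was 0.136. The unswapped 1 h arrays gave 0.404 and the turned swap alone gave -0.200 against the 50 h mean.

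**Figure D3:**
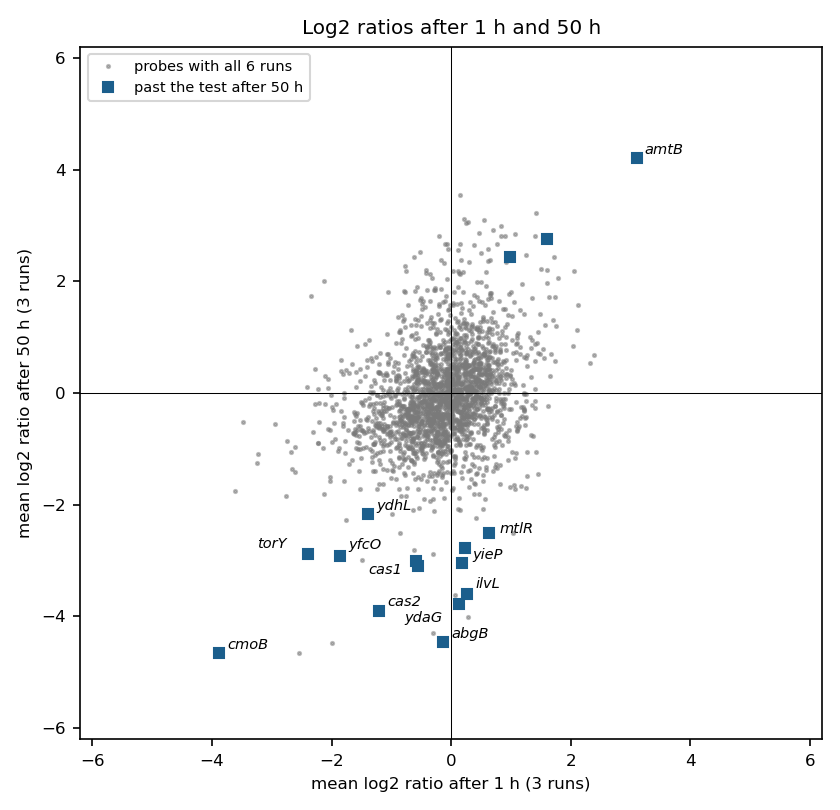
Mean log2 ratio after 50 h against that after 1 h for 2277 probes with all 6 runs (grey) and the probes past the test after 50 h (squares), both axes likely irradiated over control. amtB lay high on both axes and cmoB low on both, while ilvL, ydaG, yieP and abgB had means near 0 after 1 h, and r was 0.311.

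Of the gene lists, CRP-dependent sugar and acetate uptake had the smallest p in the list test after 50 h. List means cover the genes measured in all 6 runs, as the list test does, and are relative to the array median: of 81 list means over both times and the difference, 31 had the other sign when arrays were not centred and 23 with a dye term. For this list the mean over 20 such genes was 0.49 ± 0.35 on the log2 scale (SD over 3 runs), against 0.12 ± 0.35 after 1 h. Of its 22 tested genes, 19 had a mean above 0 after 50 h, 10 of them in all runs, and 0 genes were lower in all runs. Of all tested probes, 51.9% had 1 sign, of either direction, in all runs. The maltose transport genes malF and malK stood at 0.98 ± 0.44 and 1.12 ± 1.11, the galactitol gene gatB at 1.09 ± 1.30 and the tryptophan permease tnaB at 0.75 ± 0.71, and without run 3 malK stood at 0.50 and gatB at 0.34. The list missed the test (limma camera, adjusted p 0.059, and 0.891 with an estimated correlation), and 0 of its genes passed when adjusted over the list alone or over all genes.

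In nitrogen and sulfur supply, glutamate and ammonium assimilation had a mean of 0.30 ± 0.92 after 1 h and -0.04 ± 0.22 after 50 h, with glnE, glnB and glnL at -0.61 ± 0.19, -0.90 ± 0.75 and -0.72 ± 0.23 after 50 h, of which glnB stood at -0.20 and glnL at 0.32 with a dye term. Adjusted over the list alone, amtB passed at both times, and over all genes at 50 h only. Cysteine and sulfur assimilation had means of -0.22 ± 0.25 after 1 h over 15 genes, against 0.03 over all 25 tested at 1 h, and of 0.09 ± 0.28 after 50 h. Adjusted over the list alone, 1 of its genes passed after 1 h, the reductase cysH at 2.28 ± 0.54, and 2 after 50 h, cysD and the cystine-binding tcyJ at 2.67 ± 1.86, with 0 over all genes. Without run 2 at 50 h, tcyJ stood at 1.65 and did not pass. Methionine synthesis had means of 0.15 ± 0.59 and 0.29 ± 0.28.

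The other amino acid lists had 0 genes past the test over all genes. Means after 1 h and 50 h were -0.50 ± 0.11 and 0.52 ± 0.52 for branched-chain amino acid synthesis (-0.14 over all 10 genes tested at 1 h), where leuB stood at -1.71 ± 1.14 after 1 h and leuC at 2.65 ± 2.89 after 50 h, or 0.98 without run 2. They were 0.35 ± 1.41 and 0.13 ± 0.86 for histidine, -0.34 ± 0.05 and -0.25 ± 0.47 for aromatic amino acids, and -0.32 ± 0.65 and 0.04 ± 0.54 for arginine. Threonine, lysine and diaminopimelate synthesis, with 4 genes tested at 50 h, was left out of the list test. Its means over the tested genes were -0.18 after 1 h (10 genes) and 0.54 ± 0.49 after 50 h. The gene dapB at 2.18 ± 1.5 after 50 h was the 1 gene past the test adjusted over the list alone. Purine and pyrimidine synthesis had means of -0.56 ± 0.72 and 0.11 ± 0.37.

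In the oxidative stress lists, the OxyR regulon had means of -0.80 ± 0.29 after 1 h and -0.45 ± 0.13 after 50 h over 11 genes. The 1 h mean was pulled down by ahpC and ahpF: the median was -0.32, and over all 17 genes tested at 1 h the mean was -0.22 and the median -0.10, with 7 genes above 0 and 10 below. Adjusted over the list alone, 3 of its genes passed after 1 h, namely ahpC, ahpF and the glutaredoxin grxA at 1.99 ± 0.51, with 0 over all genes. For ahpF the turned swap had the sign of the other arrays, and for ahpC it had the opposite one. The SoxRS and MarA regulon had means of -0.55 ± 0.77 and -0.20 ± 0.71, and the aconitase acnA passed at both times adjusted over the list alone, at -1.28 ± 0.40 and -1.40 ± 0.13. With a dye term acnA stood at -0.84 and -0.75 and passed at neither time in this list. The general stress genes that depend on RpoS had means of -0.07 ± 0.62 and 0.13 ± 0.29, with the catalase katE at -1.54 ± 0.42 after 50 h past the test over the list alone.

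Iron storage and heme synthesis had means of 0.18 ± 0.24 and 0.17 ± 0.14. Adjusted over the list alone, hemC passed at both times at 1.64 ± 0.23 and 1.73 ± 0.74, hemL at -1.90 ± 0.93 and hemB at -0.96 ± 0.11 after 1 h, and ftnA after 50 h, with 0 over all genes. Iron uptake under Fur had means of -0.25 ± 0.59 and 0.13 ± 0.45, with the siderophore receptor cirA at -1.70 ± 0.28 after 50 h past the test over the list alone. Iron-sulfur cluster assembly and acid resistance had too few genes for the list test, so their means are over the genes tested at each time. For iron-sulfur cluster assembly they were 0.35 after 1 h (10 genes) and -0.24 ± 0.13 after 50 h (4 genes). For acid resistance they were -0.39 after 1 h (6 genes) and -0.25 ± 0.24 after 50 h (2 genes).

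In DNA repair, the LexA-controlled genes had means of -0.18 ± 0.38 and -0.45 ± 0.23, with uvrA at -2.07 ± 0.87 and ruvA at -1.90 ± 1.82 after 50 h (-0.93 without run 3), and 0 genes passed over the list alone. Of the tested LexA-controlled genes, 7 had means above 0 after 1 h and 12 below. Among the 7 was uvrD at 1.41, or -0.16 with the swap read as already turned. After 50 h, 3 were above 0 and 9 below. Repair outside that regulon had means of -0.01 ± 0.32 and 0.29 ± 0.46, and the glycosylase alkA at -1.69 ± 0.48 and the nuclease recC at -1.5 ± 0.43 passed over the list alone after 50 h. Cryptic prophage and insertion elements had means of -0.11 ± 0.55 and 0.33 ± 0.51, and heat shock chaperones and proteases of -0.10 ± 0.23 and 0.25 ± 0.27, with 0 such genes in either.

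In central metabolism, the TCA cycle and glyoxylate shunt had means of -0.29 ± 0.17 and -0.30 ± 0.36. Adjusted over the list alone, aceA and acnA passed at both times, with aceA at -1.81 ± 0.31 after 50 h, and lpd passed after 50 h at -1.71 ± 0.49, but with a dye term lpd stood at 0.99, so its direction rests on leaving out the dye. Glycolysis and the pentose phosphate pathway had means of -0.29 ± 0.32 and -0.04 ± 0.24. After 50 h, 4 of its genes passed over the list alone, with pyruvate kinase pykA at 2.84 ± 1.93, aceE at 1.25 ± 0.59, eda at -1.38 ± 0.50 and gapA at -1.40 ± 0.44. The other gapA probe lacked a run at 50 h and had values of 0.31 and 2.96. NADH dehydrogenase, oxidases and ATP synthase had means of -0.09 ± 0.12 and -0.04 ± 0.43, with atpB at -1.65 ± 0.58 after 1 h past the test over the list alone, and anaerobic respiration of -0.24 ± 0.47 and -0.12 ± 0.22.

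Ribosomal proteins had means of -0.04 ± 0.33 and -0.04 ± 0.21, and translation factors with aminoacyl-tRNA synthetases of -0.17 ± 0.33 and -0.22 ± 0.06. Flagella and chemotaxis had means of -0.23 ± 0.22 and 0.30 ± 0.33, with flgA at 2.77 ± 0.94 after 1 h, and 0 of its genes passed over the list alone. Fimbriae, curli and capsule had means of 0.19 ± 0.46 and -0.08 ± 0.23, and fimF passed over the list alone after 50 h. Outer membrane and envelope stress had means of -0.35 ± 0.45 and -0.36 ± 0.28, with psd at -1.47 ± 0.32 and ompX at -1.36 ± 0.62 after 1 h and the sigma factor rpoE at -1.35 ± 0.26 after 50 h past the test over the list alone.

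The genes past the test over their list alone depended on the dye term after 50 h. With it, 2 of the 18 such genes it could test still passed over the list alone, amtB and fimF. The log2 values were at a median of 65.5% of those without it, under 50% for katE (-0.53), cirA (-0.56), gapA (-0.55) and ftnA, and of the other sign for lpd. For aceA and rpoE they were -0.92 and -0.68, and the median standard error was 0.457 against 0.348. After 1 h, 12 of 13 such genes still passed with it in at least 1 list, at a median of 95.1%, acnA in the TCA list only. This fit counts run 2 and its swap as separate replicates, and the median standard error there was 0.322 against 0.348. Without 1 run of the same time, 3 to 11 of 19 passed after 50 h and 4 to 9 of 13 after 1 h.

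Over all genes tested at a time, further list means differed from those over the genes with all 6 runs by a factor above 1.5 or in sign. After 1 h they were 0.11 for histidine, -0.31 for purines and pyrimidines, 0.03 for ribosomal proteins, -0.11 for translation factors, -0.18 for SoxRS and MarA, -0.16 for RpoS-dependent genes and -0.06 for heat shock. They were -0.02 for flagella, -0.46 for the TCA list, -0.0014 for the NADH dehydrogenase list, -0.09 for anaerobic respiration, -0.02 for DNA repair outside the LexA regulon and -0.04 for prophage. After 50 h they were -0.0082 for ribosomal proteins, -0.06 for SoxRS and MarA, 0.20 for iron uptake, -0.09 for the NADH dehydrogenase list, 0.01 for glycolysis, -0.07 for anaerobic respiration, -0.18 for the envelope list and 0.16 for DNA repair outside the LexA regulon.

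Camera in limma called 0 of 27 lists at each time and for the difference, with 2, 1 and 1 at an unadjusted p under 0.05 and smallest adjusted p of 0.412, 0.059 and 0.788. With an estimated correlation it also called 0. The directional test of fry, whether a list's genes move on balance 1 way, called 0. Its mixed test, whether they change in either direction, called 19, 19 and 6, and neither compares a list with other genes. For the difference, 2 genes of iron storage and heme synthesis, 1 of the TCA list and 1 of the envelope list passed when adjusted over the list alone, with 0 over all genes. The mean, the median and the direction in camera differed in sign after 1 h for ribosomal proteins, LexA-controlled genes, other DNA repair, RpoS-dependent genes, heat shock, prophage and the NADH dehydrogenase list, and after 50 h for the arginine, heme, TCA and NADH dehydrogenase lists. For the difference they did so for the aromatic, methionine, ribosomal, LexA, OxyR, TCA, NADH dehydrogenase, anaerobic and envelope lists.

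**Figure D4:**
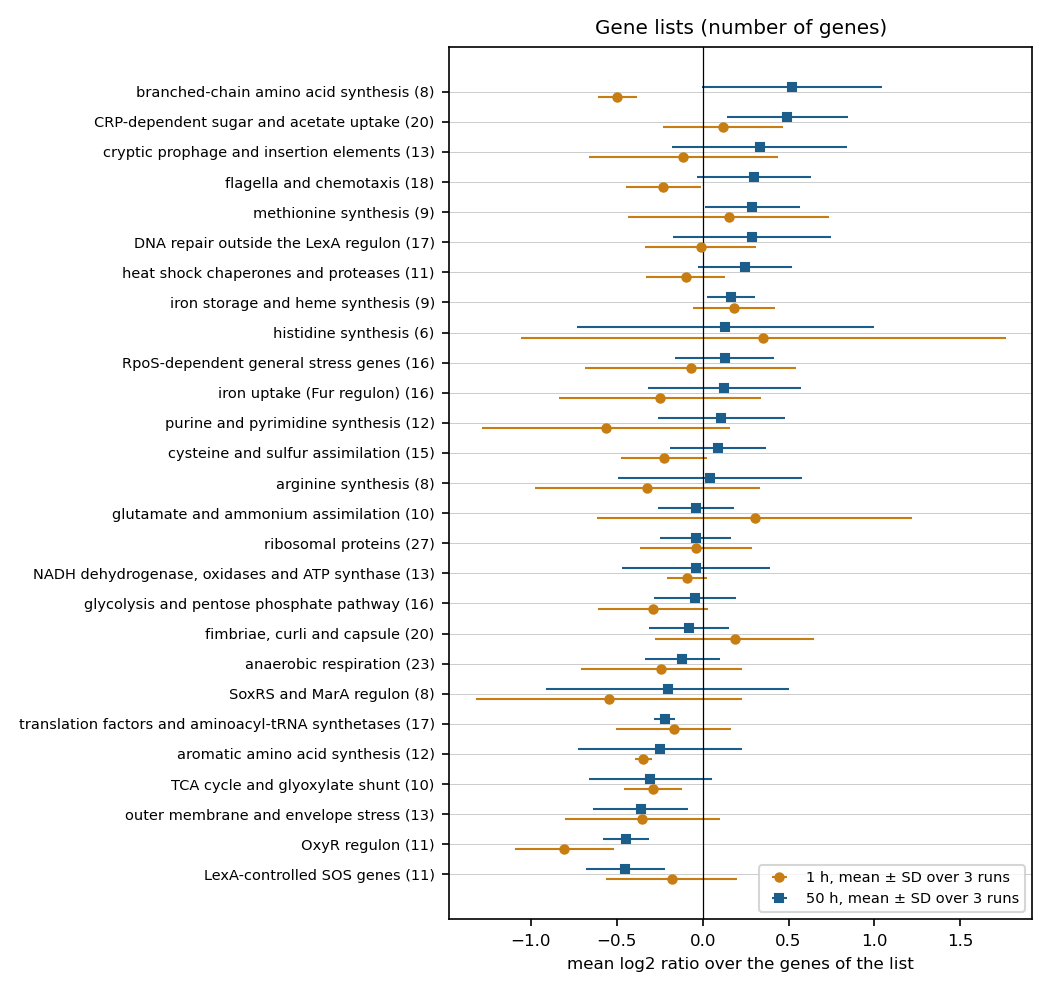
Mean log2 ratio (likely irradiated over control) over the genes with all 6 runs of each of 27 lists after 1 h (circles) and 50 h (squares), with bars for the SD over 3 runs and the number of genes in brackets. The OxyR regulon lay at -0.80 and -0.45 over 11 genes (-0.22 over all 17 tested at 1 h), CRP-dependent uptake at 0.49 after 50 h, and no list passed the test.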

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

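The dye term without a random block, named probes only, the swap read as already turned, and the correlation with the unswapped arrays only were chosen after the data were seen. Causes of changes were not tested except where stated.

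Of 16 probes past the test at 50 h, all kept their direction in each setting (with named probes only, the 12 that were tested). In most settings this was fixed in advance, as the 50 h mean is unchanged or all 3 runs have 1 sign. The direction could change with the dye term only. Without centring, values at 50 h moved by at most 0.58, and all values of the 16 at 50 h lay further from 0 than that. Quantile normalization keeps the order of values within an array. Counts from 12 to 23 came with values not centred, quantile normalization, minimum ratios kept, robust empirical Bayes, treat and the swap read as turned. The count was 5 with 1 median absolute deviation, 8 with at least 2 runs, 38 with the unswapped run 2 array only, and 0 with the swapped array only, with 50 h fitted alone and with the dye term. Under the dye term the 16 log2 values were 60% to 98.8% of those without it (amtB 3.93, cmoB -4.15, cas2 -2.34, ilvL -2.35), and the median standard error grew from 0.378 to 0.570. The calls of ydhL and mtlR ended although their log2 values stayed at 98.8% and 95.5%. All 16 kept an unadjusted p under 0.05, with adjusted p from 0.124 to 0.365 in limma. The count was 7 with named probes only, where the 4 probes without a name were left out. At 1 h the count of 0 became 3 with 1 median absolute deviation, 10 with quantile normalization, 6 with the unswapped array only and 76 with the dye term. In the fit with the dye term the swapped array carries the dye estimate, and run 2 and its swap count as separate replicates. A 2-fold rule without a test gave 407 at 1 h, 419 at 50 h and 273 for the difference, since it sets no limit on error.

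Leaving out 1 run gave 0 to 37 probes at 50 h, 0 at 1 h and 0 to 4 for the difference. At 50 h the counts were 37 without run 1 at 1 h, 12 without run 1 at 50 h, and 0 without run 2 or run 3 of either time. The 4 for the difference came without run 1 at 1 h.

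For the lists, leaving out 1 run gave 0 to 1 at 50 h (1 without run 1 or run 2 at 1 h) and 0 elsewhere. Values not centred gave 1 at 50 h, and fry's mixed test, which asks another question, gave 19, 19 and 6. Other planned list settings gave 0.

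The correlation of 50 h with 1 h (0.311) ranged from 0.136 without run 1 at 1 h to 0.387 when 1 run was left out, and was 0.716 over the 16 probes past the test, which were picked for large values. Among 5559 values of named genes in alternatives, 120 lost and 51 gained the test, and 226 not past it moved by more than the spread. Signs changed in 83, none past the test in either setting, with 28 under the dye term, 15 with values not centred and 12 with the swap read as already turned. Of these 83, 17 belonged to values of at least 1 in size, such as lpd at 50 h, from -1.71 to 0.99, and ahpC at 50 h, from -1.75 to 0.70, both under the dye term. Of 918 list values, 47 gained the test, and means changed sign in 107, including 31 of 81 not centred and 23 of 81 under the dye term, with 0 past the test.

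With run numbers as a block the difference and the lists still gave 0. The runs of both times share only a number, and deviations of runs with the same number correlated with -0.051, -0.068 and -0.022.

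Not run were the dye term with a random block, whose correlation was estimable for 0 of 2229 probes, each time alone for the difference, and the swap's correlation among genes past the test at 1 h without run 2, of which there were 0. Signal over background was not used here.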

Other observations

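All tests in this part were chosen after the results were seen.

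Some neighbouring genes stood low together, though most of them missed the test and no test of stretches was run. At 50 h relA (-1.60 ± 0.60) stood beside the toxin-antitoxin genes mazE (-1.27 ± 0.77) and mazF (-1.89 ± 0.91), which follow it on the chromosome, and none of them passed. Also low at 50 h were hsrA (-2.07), yieP (-3.05), maoP (-2.81), yifB (-3.62) and ilvL (-3.60), of which yieP and ilvL passed. These genes form a stretch in the chromosomal order of genes with a probe, but the locus tags of yieP (b3755) and maoP (b3764) are not consecutive. At 1 h their means were nearer to 0 with wide spreads, with SDs of 1.05 for hsrA, 1.17 for yieP, 4.62 for maoP, 1.91 for yifB and 1.28 for ilvL. The turned swap stood at 1.21, 1.36, 7.10, 3.89 and 2.35 for these genes, so as deposited it was low across the stretch like the 50 h arrays, and a dye effect is not excluded for it. At 1 h argP (-2.61 ± 0.82), scpA (-2.24 ± 0.84) and scpB (-1.81 ± 0.58), which are neighbours, were low, and none passed. They share a printed position with der (-1.59 ± 0.59), which is not close to them on the chromosome. Such positions, with at least 3 measured probes all beyond 1.2 in 1 direction, numbered 3 of 481 at 50 h and 1 of 936 at 1 h.

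The 2 probes of a gene disagreed in sign more often than they agreed, at both times. Genes with 1 probe cannot be checked in this way. Among genes with both probes measured in all runs, 16 of 40 had probe means of 1 sign at 1 h and 3 of 8 at 50 h. Of the glnS probes, 1 stood at -0.16 ± 0.21 and the other at -2.03 ± 0.66 at 1 h. Whether the annotation of the extra probes is right was not tested.

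By the reading of the identifiers, neighbouring genes share a printed position, so shared transcription and an effect of the position may both make their ratios alike. At 1 h, pairs up to 3 genes apart correlated by 0.101 (SE 0.0249) more at the same position than at other positions, which is consistent with an effect of the position. Pairs at other positions still correlated by 0.0795 (SE 0.0213), as shared transcription needs. At 50 h the pairs at other positions correlated by 0.0871 (SE 0.0331), and the same position added 0.02 (SE 0.0390) in the mean, with 0.101 (SE 0.0295) in run 1, -0.0195 (SE 0.0366) in run 2 and 0.0204 (SE 0.0311) in run 3, which leaves an effect of the position open. The low pairs at cas1 and cmoB therefore cannot be told apart from an effect of the printed position at 50 h. The low genes around ilvL span 2 positions, which 1 position alone does not cover. Both positions lie in the same printed row, however, and an effect of a row was not tested, so it stays open for these genes.

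The correlation of 1 h with 50 h (r = 0.311) may reflect a dye effect of each gene, since the 50 h arrays and most 1 h arrays share 1 dye orientation. The turned swap correlated with the 50 h mean by -0.200, as a dye effect needs and a shared response alone does not. With the dye effect balanced out, the 1 h values correlated with 50 h by 0.0021 (run 2 in both orientations) and by 0.007 (all 1 h arrays in the fit with a dye term), while the dye coefficient itself correlated with 50 h by 0.409. These values show no shared response but do not exclude one, as each rests on the 1 swapped array. The reading of the swap as not yet turned also enters here: read as already turned, r was 0.448.

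The 16 probes past the test at 50 h could also carry a dye effect. As deposited, the swap at 1 h had the sign of the 50 h value in 11 of the 16, against 57.9% of all tested probes, with a median ratio of 0.33 to the 50 h value among the 11. In the other 5 (amtB, cmoB, torY, yfcO and ydhL) the turned swap had the sign of the 50 h value, but if the swap had been turned before deposit, these 5 would be the ones that follow the dye. With a dye term all 16 kept their direction at 60% to 98.8% of their log2 value, least reduced for ydhL (98.8%), mtlR (95.5%) and amtB (93.5%) and most for cas2 (60%). The dye estimate rests on the 1 swapped array and on its turning, so a dye effect cannot be told apart from a response for any of the 16 without a swap at 50 h.

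The 3 runs at 50 h allow 4 sign patterns, too few for a share under 0.05: the real one gave 16 and the highest other gave 0, so 1 of 4 gave as many. At 1 h all 4 of 4 gave 0, the highest other being 0, and for the difference all 10 of 10 splits gave 0, again too few for a share under 0.05.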
